A study of Mus musculus with 21 samples.

How the data were processed

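The series measured GATA4 occupancy (bioChIP), open chromatin (omni-ATAC) and polyadenylated RNA in mouse ventricles at embryonic day 12.5, in 21 samples of 8 groups taken from the sample labels. The 2 cardiomyocyte ATAC samples were not analysed here. RNA values were deposited as read counts per gene, made with featureCounts 1.6.3 counting forward-stranded reads on mm10 genes, per the file headers. STAR 2.7.3a, Bowtie 1.1.1, Bowtie2 2.2.9, MACS2 2.2.4 and deepTools 3.3.1 are also named in the submitters' processing notes, which do not give their roles. EC and CM RNA were both labelled polyadenylated RNA; how the cardiomyocytes were isolated is not given in the sources used here. Peaks were deposited as 1 list per library, with peak names that carry MACS2, per the peak names in the deposited files. Each peak came with a fold over background and with −log10 p and −log10 q values, as deposited; whether a control library was used is not given in the sources used here. Peak fold and q served only to rank or filter peaks within a list. The EC-only count table held the same values as the EC columns of the joint table in all 48842 cells, so it added no data.

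Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg, threshold 0.05). Standard errors are the log2 fold change divided by the root of F. DESeq2 1.42.0 was the other tool. Gene lists (21, with 411 entries) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. No replicate pair agreed within sampling noise: chi-square per degree of freedom was 8.36 for the EC pair and 15.1 to 38.5 for CM pairs. RefSeq symbols matched 95.0% of the 24421 genes. Counts were simulated for 14851 genes of the EC and CM comparison, with 200 genes changed per run. The test recovered 65.0% of genes changed 1.5-fold, 86.4% changed 2-fold and 93.2% changed 4-fold, with 6.33 false calls per run. In the data 11547 genes were called, far more than were changed in a run, so these rates are not the error of that result.

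Peaks were analysed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9. Peaks of all libraries compared were merged where they shared at least 1 bp. A region was selective with a peak in at least 2 of 3 libraries of a group and in 0 of the other group, and shared with at least 2 of 3 in both. Presence in a list depends on depth and peak calling in that library, and a missing peak is not proof of closed or unbound chromatin. Regions were given to the nearest transcription start within 50 kb, taking the outermost exon end of each gene in the count table. From this step 144 genes on several chromosomes or strands were left out, as were 176 symbols whose copies lie apart on a chromosome (span over 100 kb beyond RefSeq, or a gap over 500 kb where RefSeq had no match). The latter filter was added after false host genes were seen. Exons and introns come from the same table, which does not mark UTRs. Coordinates are mm10, counted from 1. Odds ratios have 95% Woolf intervals. In simulated lists, all 500, 300 and 2000 planted regions of the 3 classes were recovered. Each planted region met the rule of its class by construction, and list lengths were not made unequal. This checks the code only and gives no accuracy for the real lists. Matched regions without GATA4 overlapped no GATA4 region and were weighted over 10 classes of peak strength like the EC-open regions with GATA4 (12868 of 101038).

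Main tests, alternatives, lists and the rule for named items were fixed before the data were examined; alternatives added later are named as such in the closing section. Named genes were the 11 GATA genes and cofactors, up to 3 members per list called by camera with the smallest adjusted p, and the 5 greatest differences each way among genes with at least 20 CPM in every library of the higher group. Named regions were the 5 strongest per selective class, regions at Gata4 and up to 4 per class at endothelial, endocardial and cardiomyocyte lists. Alternatives were other scalings, no count filter, a 2-fold test, stricter peaks (−log10 q of at least 5), equal list length (strongest by p), a peak covering 0.5 of its region, 3 of 3 libraries, distances of 20 and 100 kb, the replicate block and each library left out. The planned motif tests (12 motifs) need a genome sequence and were not run. With 3 libraries against 3, an exact two-sided p cannot go below 0.1.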

Results

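Ventricles of E12.5 mouse hearts were profiled to compare where the transcription factor GATA4 sits in the endothelial and the cardiomyocyte lineage. GATA4 was biotinylated only in cells with Cre activity and pulled down with streptavidin (bioChIP), using Tie2-Cre for endothelial and endocardial cells, a driver also active in blood cells, or Tnnt2-Cre for cardiomyocytes. Each lineage had 3 GATA4 libraries of 15 to 20 hearts. Open chromatin was mapped by ATAC in 2 libraries of 40000 sorted Tie2-Cre endothelial cells (EC). A further 6 ATAC libraries of 20000 sorted EC each came from embryos labelled Gata4 het or Gata4 ko, 3 per genotype, after 1 mg of tamoxifen at embryonic day 9.5 had activated a Cdh5-driven Cre. RNA was sequenced from EC in 2 libraries of 60000 sorted cells and from cardiomyocytes (CM) in 3 libraries. Cardiomyocyte ATAC (2 samples) was not analysed here. Nothing in the labels says whether replicates came from separate litters, so p-values of tests between libraries measure the spread between these samples. Fisher's exact tests take genes or regions as units, and their p-values do not measure that spread.

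Sequencing depth differed between the RNA groups. Reads counted on genes came to 27660790 and 21682362 in EC and to 48393473, 42948614 and 45522886 in CM. GATA4 peak lists held 17682, 2734 and 25936 peaks in the Tie2-Cre replicates 1 to 3 and 22814, 3603 and 30447 in the Tnnt2-Cre replicates 1 to 3. The second library of each lineage was thus far shorter than the rest. Peak numbers were 114599 and 130708 in Tie2-Cre EC ATAC, 90326, 82612 and 67201 in het and 87496, 79263 and 55733 in ko (replicates 2, 3 and 4).

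The first comparison asked how EC and CM transcriptomes differed, as the setting for GATA4 occupancy. Endothelial genes were higher in EC and contractile genes higher in CM, with GATA4 itself higher in EC. Gata4 (chromosome 14, 63198915 to 63245260, mm10) stood at 248 ± 6.37 CPM (read counts scaled to library size) in EC (SD, n = 2) and 75.6 ± 11.9 in CM (SD, n = 3), a log2 fold change of 1.72 (SE 0.11, adjusted p = 1.29e-07, edgeR quasi-likelihood test). Gata6 differed by 1.56, Gata5 by 2.91, Gata2 by 4.74 and Gata3 by 5.41 on the log2 scale. The cofactor gene Zfpm1 was also higher in EC, by 2.40, while Zfpm2 was higher in CM (log2 fold change -0.54). Tal1, Lmo2 and Ldb1, whose products form complexes with GATA factors in blood and endothelial cells, were higher in EC by 2.94, 1.94 and 1.14. Gata1, an erythroid factor, had 0.449 CPM in EC and 0.472 in CM and did not pass the test. Of the 11 GATA genes and cofactors, 9 were thus higher in EC and 1 lower. In all, 5575 genes were higher and 5972 lower in EC among 14851 tested, of which 3301 and 3355 differed at least 2-fold.

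All 24 endothelial genes were higher in EC, with a median log2 fold change of 2.58. Among them Eng, a TGF-beta co-receptor, stood at 621 ± 20.6 CPM in EC and 34.6 ± 2.99 in CM, and Cdh5, the junctional VE-cadherin, at 1017 ± 20.3 and 73.9 ± 9.17. Vwf, encoding von Willebrand factor, was higher by 3.28. All 23 measured endothelial transcription factor genes were higher as well, among them Nfatc1 (3.96) and Elk3 (3.38). Of the 20 endocardial genes 19 were higher and 1, Cytl1 (-1.14), was lower; members named here and below as running against their list were chosen after their values were seen. Hapln1, a hyaluronan-linking matrix protein, reached 1473 ± 26.0 CPM in EC against 25.9 ± 2.11 in CM, and Wnt4 was higher by 5.21. Cushion mesenchyme genes followed, with 15 of 16 higher, among them Sox9 (6.27), Twist1 (4.35) and Snai2 (4.20), and 1, Dcn (-2.54), was lower. Of the 18 coronary and vascular endothelial genes 13 were higher, including Gja4 (4.13), Nr2f2 (3.30) and Mecom (2.34), and 4 were lower, namely Cd36 (-4.68), Gja5 (-3.82), Apln (-2.03) and Fabp4 (-1.71).

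Signalling and matrix genes were mostly higher in EC. Notch genes were higher in 12 of 16 cases, with Notch1 at 3.34, Notch3 at 2.90 and Notch4 at 2.33 on the log2 scale, and lower in 3, namely Hey2 (-2.83), Jag2 (-1.29) and Lfng (-1.17). BMP and TGF-beta genes were higher in 15 of 21 cases, among them Tgfb1 (4.98) and Tgfbr2 (2.24), and lower in 2, the ligand genes Bmp7 (-6.18) and Bmp10 (-5.75), whose differences were the greatest of the list. VEGF and angiopoietin genes were higher in 11 of 15 cases, including Plxnd1 (3.41) and the VEGF receptor gene Kdr (2.66), and lower in 3, the ligand genes Angpt1 (-3.51), Vegfa (-2.88) and Vegfb (-1.56). Basement membrane and matrix genes were higher in 16 of 19 cases, with Has2, a hyaluronan synthase, at 103 ± 4.74 CPM in EC and 6.43 ± 0.600 in CM, and Nid1 at a log2 fold change of 2.76, and 1, Nid2 (-1.35), was lower.

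Cardiomyocyte genes made the opposite set. All 26 sarcomere genes were lower in EC, with a median log2 fold change of -6.70. Myh6, a myosin heavy chain gene, stood at 7153 ± 540 CPM in CM and 44.4 ± 1.88 in EC, Mybpc3 at 3239 ± 66.6 and 27.9 ± 3.65, and Actn2 at 782 ± 36.7 and 16.8 ± 0.135. All 19 measured calcium-handling and ion channel genes were lower, including Pln (-8.60), Ryr2 (-6.63) and Slc8a1 (-6.44). Of the 21 cardiomyocyte transcription factor genes 16 were lower, including Irx4 (-7.12), Ankrd1 (-6.00) and Smyd1 (-5.78), and 5 were higher, namely Gata4, Gata6, Mef2d (71.1 CPM in EC and 23.4 in CM), Hand2 (1.27) and Tbx20 (0.59). Energy metabolism moved with them. All 21 oxidative phosphorylation genes, 18 of 20 fatty acid oxidation genes and 18 of 20 glycolysis genes were lower in EC, among them Cox7a1 (-6.11), Cycs (-3.31), Fabp3 (-6.46), Cd36 (-4.68), Eno3 (-5.30) and Pfkp (-4.99). Higher were the glycolysis genes Eno1 (3.40) and Gapdh (0.90) and the fatty acid oxidation gene Cpt1a (0.60).

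**Figure D1:**
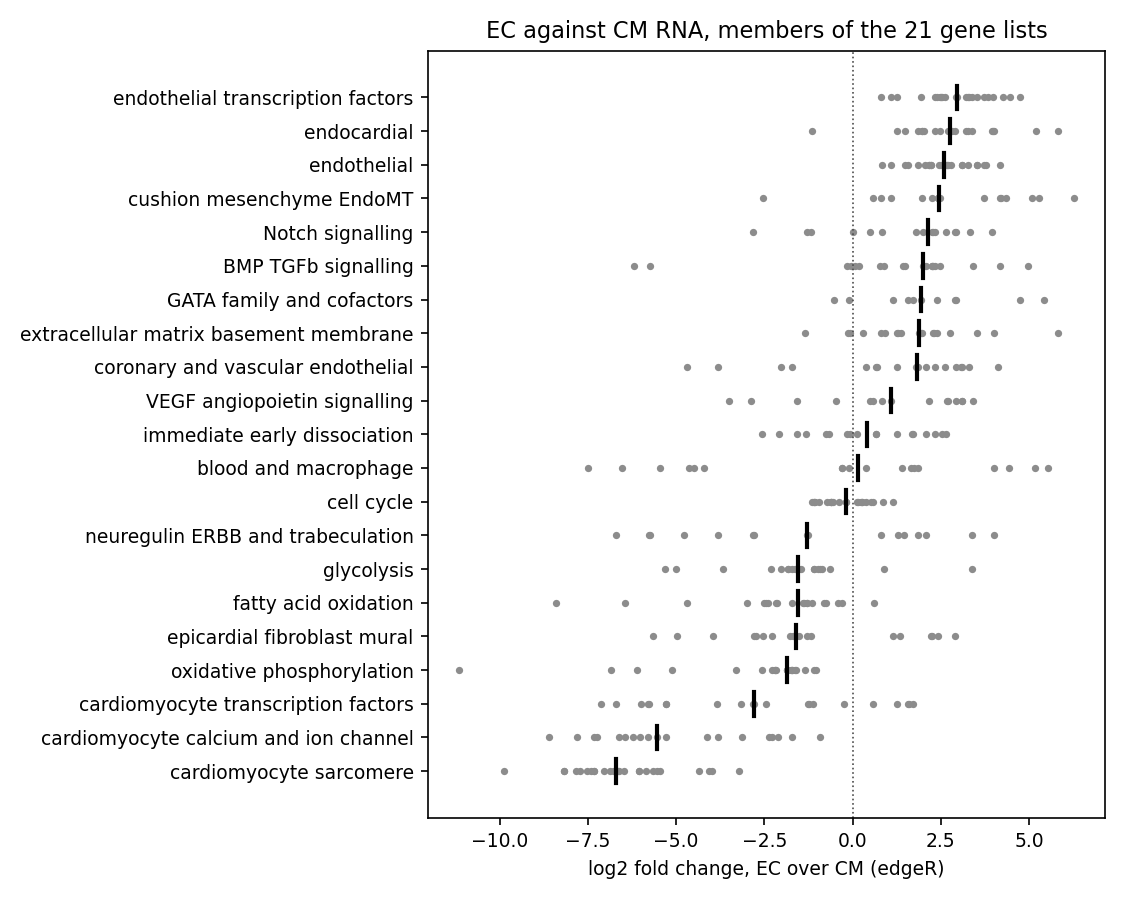
Each grey point is a gene, placed by its log2 fold change of EC over CM (x axis), in the 21 fixed gene lists (y axis), and black bars mark list medians. Sarcomere genes lie farthest to the left, with a median of -6.70, and endothelial transcription factor genes farthest to the right, with a median of 2.97.

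The preset-correlation set test (camera) called 10 lists higher and 6 lower in EC. With an estimated correlation none of the 16 passed (4 higher and 3 lower at an unadjusted p under 0.05). The adjusted p was 0.111 for the endothelial, endocardial, endothelial transcription factor, BMP and TGF-beta, sarcomere, calcium and fatty acid lists, and lay between 0.167 and 0.270 for the other 9 with an estimated correlation. Counted adjusted over the list alone, each of the 16 lists gave the same numbers except fatty acid oxidation, with 19 lower. The other 5 lists were not called by camera, although fry, which does not compare a list with other genes, called 3 of them lower in EC (epicardial, neuregulin and cell cycle). Blood and macrophage genes split, with 8 higher and 6 lower in EC of 18 measured (camera adjusted p = 0.688), and their median of 0.15 and mean of -0.41 differed in sign, as did the directions of camera and fry. Epicardial, fibroblast and mural genes had 5 higher and 12 lower of 18 (camera adjusted p = 0.0964). Neuregulin and trabeculation genes had 7 higher and 9 lower, cell-cycle genes 8 and 11, and dissociation-induced immediate early genes 9 and 6, with camera adjusted p of 0.635, 0.495 and 0.501. Endothelial transcripts were not absent from CM: the CM level of the 24 endothelial genes had a median of 16.8% of their EC level, between 5.58% for Eng and 55.6% for Cldn5, whereas sarcomere transcripts in EC had a median of 0.993% of their CM level. The labels give no batches for the RNA.

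Among genes with at least 20 CPM in each library of the higher group, the greatest differences were for Gp1ba (6.64), Ecm1 (6.51), Sox9, Sall3 (5.94) and Hapln1 on the EC side. On the CM side they were Ckm, Mirlet7a-1, Hist1h2bp, Ppp1r3a and Rnu12, with 1, 1, 1, 2 and 5 counts over both EC libraries. The CM to EC ratio of Ckm, muscle creatine kinase, was 6069 (exact 95% interval 1089 to 2.4e+05, for counting error only here and below). It was 2084 (374 to 8.23e+04) for Mirlet7a-1 and 1848 (332 to 7.3e+04) for Hist1h2bp. Ppp1r3a had a ratio of 1220 (338 to 1.01e+04) and Rnu12 of 1089 (467 to 3354). The EC counts lay in replicate 2 alone for Ckm and Mirlet7a-1 and in replicate 1 alone for the others, and without that library the EC count was 0. With each library left out the fitted log2 fold change ranged from -15.28 (without EC replicate 2) to -11.30 (without EC replicate 1) for Ckm and from -13.73 to -9.75 (the same libraries) for Mirlet7a-1. It ranged from -13.50 (without EC replicate 1) to -9.91 (without EC replicate 2) for Hist1h2bp and from -13.90 to -9.37 (the same libraries) for Ppp1r3a. For Rnu12 it ranged from -15.02 (without EC replicate 1) to -9.19 (without CM replicate 1), with -9.20 without EC replicate 2, and Ckm stood at -11.56 without CM replicate 3. A value fitted against a count of 0 depends on the prior count and is no bound. Ckm and Rnu12 varied within CM: Ckm had 69.5, 72.3 and 222 CPM in replicates 1 to 3 and Rnu12 had 195, 58.0 and 62.2. Mirlet7a-1, Hist1h2bp and Rnu12 belong to small or multicopy RNA classes, whose reads can be shared among copies. Of the small nuclear and nucleolar RNA genes tested, 78 of 98 were lower and 4 higher in EC, and of the histone genes 57 of 60 were lower and 3 higher. EC libraries in turn had 5.77% and 5.34% of counts on the ribosomal precursor Rn45s, against 0.118% to 0.200% in CM.

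The next question was where GATA4 bound in each lineage. Merging the peaks of the 6 libraries gave 49798 regions. Of these, 6095 were Tie2-Cre-selective, with a peak in at least 2 of 3 Tie2-Cre libraries and none in Tnnt2-Cre libraries. Another 9086 were Tnnt2-Cre-selective and 6535 were shared. Selective regions made up 42.7% of the 14268 reproducible Tie2-Cre regions and 48.7% of the 18667 reproducible Tnnt2-Cre regions. Shared regions lay closer to genes: 25.9% were within 1 kb of a transcription start site, compared with 4.76% of Tie2-Cre-selective and 7.21% of Tnnt2-Cre-selective regions. Introns held 42.4% of Tie2-Cre-selective, 50.7% of Tnnt2-Cre-selective and 39.7% of shared regions.

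The strongest Tie2-Cre-selective region, by peak signal rank in all 3 libraries, lay on chromosome 16 (23217981 to 23218952, mm10) between genes, 6274 bp from the start of St6gal1, which was higher in EC by 2.69. The others lay in an intron of Adgrg6 (chromosome 10, 14483127 to 14483648) and between genes on chromosome 14 (62216757 to 62217384, nearest Dleu7), chromosome 8 (102945423 to 102946053, nearest Cdh11) and chromosome 10 (118064869 to 118065326, nearest Mdm1). The 5 strongest Tnnt2-Cre-selective regions lay in introns of Macrod2 (chromosome 2, 140884991 to 140885693), Nav1 (chromosome 1, 135524245 to 135524985), Rtn1 (chromosome 12, 72343569 to 72344051) and Cd36 (chromosome 5, 17880768 to 17881260) and between genes on chromosome 12 (73781264 to 73781994, 126239 bp from Hif1a). Cd36, a fatty acid transporter gene, was lower in EC (log2 fold change -4.68), as were Hif1a (-2.12) and Flrt3 (-0.46), whose start was the nearest to the Macrod2 region, whereas Nav1 and Rtn1 were higher in EC, by 1.31 and 5.19. At Gata4 itself, a shared region lay 10950 bp from its start (chromosome 14, 63255933 to 63256488), with a peak in 2 Tie2-Cre and 3 Tnnt2-Cre libraries. An intronic Gata4 region (63231136 to 63231527) was Tnnt2-Cre-selective, in 2 libraries.

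Libraries of a lineage resembled each other more, on average, than those of the other lineage. The mean Jaccard index of peak bases was 0.230 within and 0.132 between lineages, a difference of 0.0980 (exact permutation test over 10 splits, one-sided p = 0.1, the smallest it can give), and of 0.247 with lists of equal length. Single pairs did not all follow: Tie2-Cre replicate 2 was closer to Tnnt2-Cre replicate 2 (0.109) than to Tie2-Cre replicate 3 (0.0985). Tie2-Cre replicate 3 was closer to Tnnt2-Cre replicates 1 and 3 (0.209 and 0.218) than to Tie2-Cre replicate 2. Tie2-Cre replicate 1 was also closer to Tnnt2-Cre replicates 1 and 3 (0.193 and 0.187) than to Tie2-Cre replicate 2 (0.135). With lists of equal length each pair within a lineage (0.292 to 0.541) exceeded each pair between lineages (0.103 to 0.166). The region counts depended on which libraries were kept, because the second libraries were short. Tie2-Cre-selective regions numbered 863 and 812 without Tie2-Cre replicate 1 or 3, and Tnnt2-Cre-selective regions 1209 and 1167 without Tnnt2-Cre replicate 1 or 3; with lists of equal length the 2 classes had 1375 and 1444 regions.

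**Figure D2:**
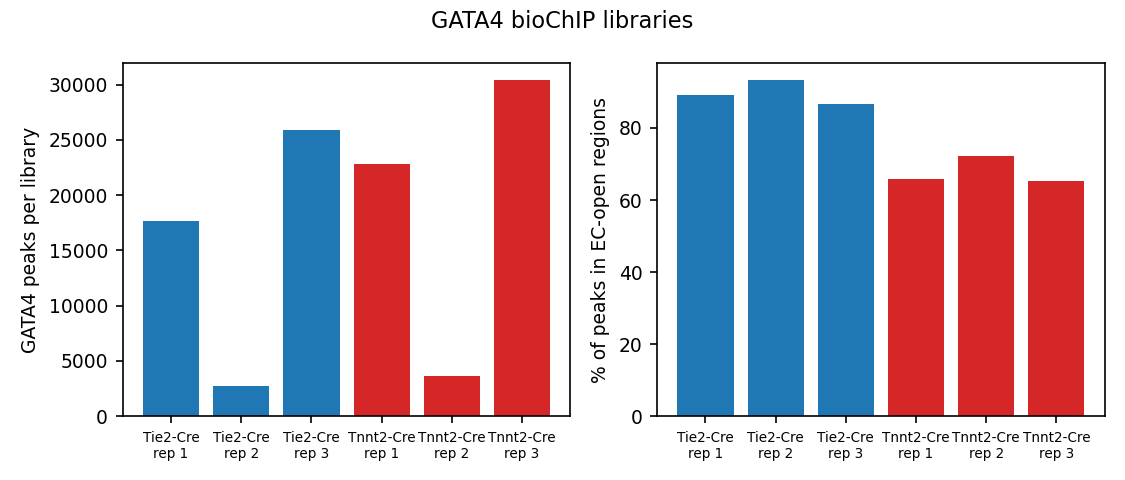
Bars show, for each GATA4 library (x axis, 3 per lineage), the number of peaks (left) and the percentage of them in regions open in both Tie2-Cre EC ATAC libraries (right). The second libraries held 2734 and 3603 peaks, and the open share was 86.6% or more in Tie2-Cre and 72.1% or less in Tnnt2-Cre libraries.

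Selective regions were then set against expression. Genes near Tie2-Cre-selective regions were mostly EC-higher, and genes near Tnnt2-Cre-selective regions mostly CM-higher. Of the called genes with only Tie2-Cre-selective regions within 50 kb, 796 were higher in EC and 365 higher in CM (68.6% EC-higher). Of those with only Tnnt2-Cre-selective regions, 746 and 1280 were (36.8% EC-higher). The odds ratio was 3.74 (95% interval 3.21 to 4.36, Fisher's exact test, two-sided p = 1.13e-67); genes are not independent replicates. It rose to 5.51 and 5.71 without Tnnt2-Cre replicate 1 or 3.

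The same division appeared at the fixed lists. Regions were counted here, and several can lie near 1 gene, so they are not independent replicates. The 24 Tie2-Cre-selective endothelial regions lay at 15 genes. Tnnt2-Cre-selective regions lay at 15 sarcomere and 17 calcium and ion channel genes. They lay at 13 cardiomyocyte transcription factor genes, with 6 regions at Tbx5, and at 9 glycolysis genes, with 6 at Hk2. Endothelial genes had 24 Tie2-Cre-selective and 5 Tnnt2-Cre-selective regions (odds ratio 7.18, adjusted p = 7.34e-05, Fisher's exact test). Examples were regions beside Icam2 (chromosome 11, 106382534 to 106383308, 279 bp from its start) and Tek (chromosome 4, 94738801 to 94739619, 80 bp). Tek is the receptor gene that names Tie2 and the Tie2-Cre driver, and whether driver DNA added to this peak was not tested. Cushion mesenchyme genes had 10 and 2 (adjusted p = 0.0175) and endothelial transcription factor genes 15 and 7 (adjusted p = 0.0264), among them a region in an intron of Hhex (chromosome 19, 37435467 to 37435982). Sarcomere genes had 2 and 30 (odds ratio 0.0991, adjusted p = 0.000329), including Tnnt2-Cre-selective regions in Actn2 (chromosome 13, 12313569 to 12314204) and 104 bp from Mybpc3 (chromosome 2, 91117825 to 91118257). Near Myh7, a Tie2-Cre-selective region (chromosome 14, 55002328 to 55002969) and a Tnnt2-Cre-selective region (55003829 to 55004958) lay close together. Calcium and ion channel genes had 5 and 29 (adjusted p = 0.0136), cardiomyocyte transcription factor genes 4 and 25 (adjusted p = 0.0154), with 2 of the latter beside Nkx2-5 on chromosome 17 (26813337 to 26814047 and 26868669 to 26869240), and glycolysis genes 1 and 17 (adjusted p = 0.0136). Endocardial genes had 12 and 9 (adjusted p = 0.322), with a Tie2-Cre-selective region in an intron of Nrg1 (chromosome 8, 31884553 to 31884923). No list passed with peak lists of equal length (smallest adjusted p = 0.0524; 2 and 2 lists at an unadjusted p under 0.05), with peaks needed in 3 of 3 libraries (0 and 2 lists) or without Tie2-Cre replicate 1 or 3 (0 lists at an unadjusted p under 0.05, Fisher's exact test). Without Tnnt2-Cre replicate 1 or 3, 0 lists passed with more Tie2-Cre-selective regions, also unadjusted, and 3 with more Tnnt2-Cre-selective regions.

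Occupancy was compared with open chromatin of EC. Tie2-Cre-selective regions were mostly open in EC, and Tnnt2-Cre-selective regions less often. Of the 6095 Tie2-Cre-selective regions 88.5% overlapped a region open in both EC ATAC libraries, against 41.9% of the Tnnt2-Cre-selective and 94.1% of the shared regions. The odds ratio between the selective classes was 10.7 (95% interval 9.79 to 11.7, Fisher's exact test), with regions not being independent replicates. It was 18.3 with equal list length, 18.6 without Tie2-Cre replicate 1 and 28.1 with peaks needed in 3 of 3 libraries. With equal list length 97.2% of Tie2-Cre-selective, 65.2% of Tnnt2-Cre-selective and 96.7% of shared regions were open. Per library, 89.7% ± 3.41 of Tie2-Cre and 67.8% ± 3.76 of Tnnt2-Cre peaks were open (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest 3 against 3 can give).

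The last comparison asked what happened to EC chromatin in Gata4 ko. No RNA of these embryos was analysed, so the deletion was not checked by expression. At Gata4, the promoter region (chromosome 14, 63245121 to 63246147) had a peak in all 3 het and all 3 ko libraries, and 2 intronic regions (63222732 to 63222994 and 63232561 to 63233039) had peaks in 2 het and 0 ko libraries, at mean signal percentiles of 2.02 and 14.6 within the libraries with a peak. Another intronic region (63225482 to 63225710, percentile 49.1) had a peak in 0 het and 1 ko libraries, and a further one (63222052 to 63222473) in 1 of each. Of 128146 merged regions, 58286 had a peak in at least 2 of 3 libraries of both genotypes (39331 in all 6 libraries), 3905 were het-selective and 2200 ko-selective. The strongest het-selective regions lay in introns of Pnpla7 (chromosome 2, 25000855 to 25001192) and Tcf4 (chromosome 18, 69507632 to 69508155) and between genes nearest Tnc (chromosome 4, 64492621 to 64492959), Map3k7cl (chromosome 16, 87533942 to 87534284) and Abo (chromosome 2, 26788964 to 26789511). The strongest ko-selective ones lay in introns of Rpn2 (chromosome 2, 157308368 to 157309165), Dlgap2 (chromosome 8, 14306780 to 14307059) and Gon4l (chromosome 3, 88880591 to 88880884), in an exon of Asun (chromosome 6, 146550498 to 146550866) and between genes on chromosome 15 (61102451 to 61102822). Near Gata5, a region 24456 bp from its start was het-selective in 3 libraries (chromosome 2, 180358926 to 180359345) and another was ko-selective in 2 (180350820 to 180351033).

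Het-selective regions outnumbered ko-selective ones 1.78-fold, and 2.46-fold with stricter peaks, 2.62-fold with peaks needed in 3 of 3 libraries and 1.44-fold without both replicates 4. With lists of equal length the counts were 2023 het-selective and 1969 ko-selective, a ratio of 1.03. Leaving out 1 library makes its own class smaller and the other larger by construction: the counts were 1074 and 4715 without het replicate 2, 1228 and 4288 without het replicate 3, and 2605 and 2814 without het replicate 4. The ratio rose to 19.1 and 14.3 without ko replicate 2 or 3 and to 2.75 without ko replicate 4. Libraries of a genotype were no more alike than libraries across genotypes (mean Jaccard index 0.537 within and 0.548 between, exact permutation test, one-sided p = 0.7).

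With libraries taken as unpaired, the open share of regions bound by GATA4 in the Tie2-Cre lineage did not differ between genotypes beyond the spread between libraries. An ATAC peak covered 80.5% ± 5.29 of the 14268 reproducible Tie2-Cre GATA4 regions in het and 78.1% ± 7.55 in ko (SD, n = 3 each), a difference of 2.44 percentage points (exact permutation test, two-sided p = 0.6). Paired by replicate number, het was higher in all 3 pairs (85.0% and 83.9%, 81.9% and 80.8%, 74.7% and 69.6% for replicates 2, 3 and 4). The exact sign-flip p was 0.25, the smallest 3 pairs allow. Het was also higher in all 3 pairs at the matched regions without GATA4 described below. With equal list length it was higher in 2 pairs for both sets. Of the EC-open regions with GATA4, 88.1% ± 4.86 had an ATAC peak in het and 85.7% ± 7.23 in ko, a difference of 2.43 points. EC-open regions without GATA4, matched to these on peak strength, differed by 1.91 points (79.7% ± 5.07 and 77.8% ± 6.05). At the 14268 reproducible regions the difference was 0.397 points with equal list length. It was -1.83 without ko replicate 4, where het replicate 4, the lowest het library, was kept. GATA4 regions of the Tie2-Cre lineage overlapped 192 of 3905 het-selective regions (4.92%) and 88 of 2200 ko-selective regions, against 23.0% of regions open in all 6 libraries. The odds ratio between the selective classes was 1.24 (95% interval 0.959 to 1.61, Fisher's exact test, two-sided p = 0.111). It passed the threshold at 1.35 with equal-length ATAC lists and full GATA4 lists, 1.54 without het replicate 3 and 1.35 without ko replicate 4. It also passed without Tie2-Cre GATA4 replicate 1 (2.60, from 23 het-selective and 5 ko-selective regions) or 3 (2.97, from 21 and 4). It did not pass with stricter peaks (1.11), equal lists throughout (1.04) or without both ATAC replicates 4 (1.16). Nor did it pass without het replicate 2 (0.940) or 4 (1.02), ko replicate 2 (1.15) or 3 (0.924), or Tie2-Cre GATA4 replicate 2 (1.24). Expression of genes near the classes gave no difference past the threshold: 51.8% of called genes near het-selective and 54.2% of those near ko-selective regions were EC-higher (odds ratio 0.911, 95% interval 0.747 to 1.11, Fisher's exact test, two-sided p = 0.363). None of the 21 lists differed in het-selective against ko-selective regions (smallest unadjusted p = 0.0939, Fisher's exact test, cell cycle genes with 6 and 0, adjusted p = 1.0). Endothelial genes had 6 het-selective and 4 ko-selective regions and endocardial genes 3 and 1.

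**Figure D3:**
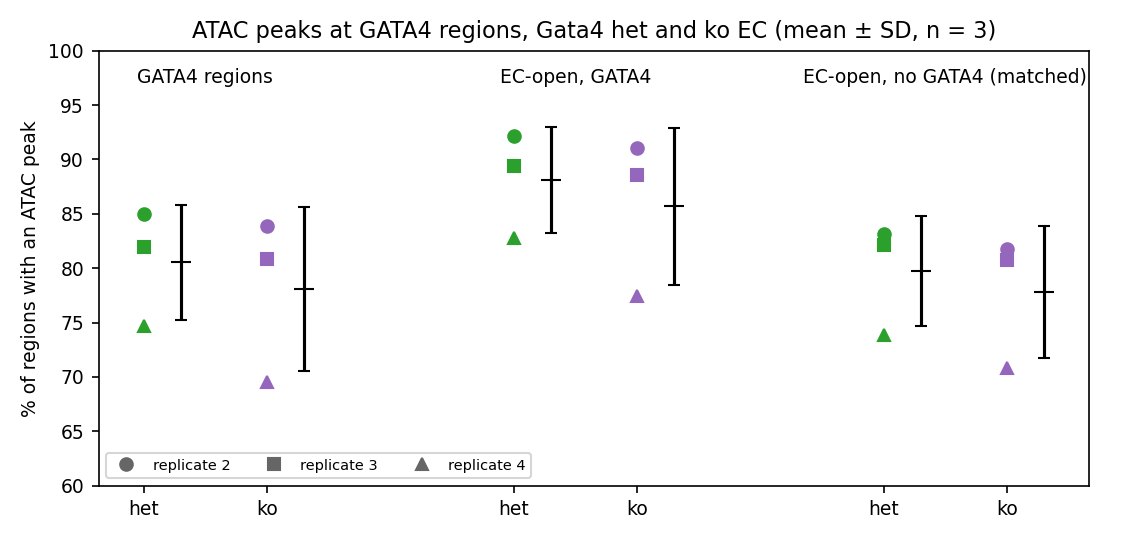
Points show the percentage of regions with an ATAC peak (y axis, from 60 to 100) in each het (green) and ko (purple) library, with marker shape giving the replicate number, for GATA4 regions, EC-open regions with GATA4 and matched EC-open regions without GATA4. Bars give mean ± SD (n = 3); replicate 4 is lowest in each set and genotype, at 74.7% in het and 69.6% in ko for GATA4 regions.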

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

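Alternatives that left out both libraries numbered 2 or 4 or the non-polyadenylated RNA classes, the occupancy test with equal ATAC lists and full GATA4 lists, and 3 of 3 libraries, 0.5-covering peaks and the block for expression, open chromatin and list regions were chosen after seeing the data. Of 717 other values of the 60 named genes, 715 kept direction and call; Zfpm2 (log2 fold change -0.54) and Ldb1 (1.14, adjusted p = 0.0651) lost their calls in the edgeR test against a 2-fold change. That test called 2569 higher and 2675 lower genes, DESeq2 5436 and 5941, and 5163 to 5437 and 5438 to 5904 with each library left out (a lone EC library is assumed to vary like CM). The median of all genes was -0.06, -0.23 without the count filter and -0.12 with DESeq2. With an estimated correlation 0 lists were called in each direction by camera (4 and 3 at an unadjusted p under 0.05), against 10 and 6 with the preset correlation, also with each library left out, and 10 and 9 with fry.

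Selective GATA4 regions (Tie2-Cre, Tnnt2-Cre) and shared ones numbered 1375, 1444 and 751 with equal list length and 798, 1156 and 689 with 3 of 3 libraries, and 3716 were shared where a peak had to cover 0.5 of its region. With each library left out they were 812 to 7337, 1167 to 11500 and 1482 to 6513. Tie2-Cre replicates 1 and 3 (863 and 812 Tie2-Cre-selective, 1514 and 1482 shared) and Tnnt2-Cre replicates 1 and 3 (1209 and 1167 Tnnt2-Cre-selective, 1883 and 1863 shared) moved them; without both numbered 2 they were 6021, 9039 and 6463. Lists with more Tie2-Cre-selective and with more Tnnt2-Cre-selective regions went from 3 and 4 to 0 and 0 with equal list length or 3 of 3 libraries and to 1 and 2 within 20 kb, 0 to 3 and 0 to 4 with each library left out (0 and 0 without Tie2-Cre replicate 1 or 3, 0 and 3 without Tnnt2-Cre replicate 1 or 3). With each library left out the odds ratio for expression was 3.14 to 5.71 and for EC open chromatin 10.7 to 18.6 (28.1 with 3 of 3 libraries); the Jaccard difference was 0.0690 to 0.127, and 0.247 with equal lists.

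Het-selective and ko-selective regions numbered 2268 and 921 with stricter q, 2023 and 1969 with equal list length, 482 and 184 with 3 of 3 libraries and 3093 and 2150 without both numbered 4. They were 1074 and 4715 without het replicate 2, 1228 and 4288 without het replicate 3, 8500 and 444 without ko replicate 2, 6821 and 476 without ko replicate 3. A class needing 2 of 2 libraries is smaller by construction. The GATA4 occupancy odds ratio ranged from 0.924 to 2.97 with each library left out, with p = 0.00186 without het replicate 3, 0.0343 without ko replicate 4 and 0.0486 and 0.0374 without Tie2-Cre GATA4 replicates 1 and 3 (Fisher's exact test). It was 1.04 (Fisher's exact p = 1.0) with equal lists throughout and 1.35 (Fisher's exact p = 0.0162) with equal ATAC lists and full GATA4 lists; the cause was not tested. The difference in open GATA4 regions was 2.44 points, and -1.83 (reversed, without ko replicate 4, the shortest list) to 5.37 with each library left out. The reversed value keeps het replicate 4, the lowest het library.

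Same-numbered correlations across regions or genes were -0.269 to 0.0332 for GATA4 and -0.0196 and -0.00878 for RNA. They gave no clear pairing by replicate number but do not exclude one. In full lists each Tie2-Cre library had its highest Jaccard index across lineages with its own number (0.193, 0.109 and 0.218 for replicates 1 to 3). With equal lists replicate 3 was nearest Tnnt2-Cre replicate 1 (0.1662, against 0.1657 for its own number). List lengths ranked alike by number in both lineages. With 2 EC libraries, the RNA values of the 2 mirror each other by construction. For ATAC they were 0.0343 to 0.115, and each library correlated best with its own number, so a pairing is not excluded there. With the replicate block, 5248 genes were higher and 5729 lower in EC (10830 of 10977 also called without it), 6305 and 9515 GATA4 regions were selective, 5849 and 3006 ATAC regions were, the Jaccard difference of 0.0980 had an exact p = 0.25 over 4 splits and the paired difference of 2.44 points an exact sign-flip p = 0.25, the smallest 3 pairs allow. Motif tests were not run.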

Other observations

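The tests on RNA classes, S phase genes and endothelial transcripts, and both counts over splits, were chosen after the results were seen; the 2 on het-selective regions were written before.

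Genes named in this paragraph were chosen after their values were seen. In the blood and macrophage list the leukocyte genes Ptprc (log2 fold change 4.02) and Cx3cr1 (5.17) were higher in EC, at 1.36 ± 0.131 and 1.70 ± 0.607 CPM (SD, n = 2), while Lyz2, a lysozyme gene of myeloid cells, was lower (-5.47). Lower in EC were also the embryonic globin genes Hbb-y (-7.49), Hba-x (-4.21) and Hbb-bh1 (-4.49) and the haem synthesis gene Alas2 (-6.54), whereas the erythroid factor gene Klf1 was higher (1.73). Among epicardial, fibroblast and mural genes, the PDGF receptor genes Pdgfra (2.41) and Pdgfrb (2.90) were higher in EC, while Msln (-5.66), Acta2 (-4.98) and Tbx18 (-2.79) were lower (edgeR, adjusted p under 0.05 for each). Of the neuregulin genes, the ligand gene Nrg1 (3.39) and the receptor gene Erbb3 (1.45) were higher in EC, and the receptor genes Erbb4 and Erbb2 were lower (-5.76 and -1.29).

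Small nuclear and nucleolar RNA and histone transcripts were lower in EC, with medians of -3.16 and -4.82 on the log2 scale against 0.00034 for protein-coding genes. More S phase cells among cardiomyocytes, as the source of a histone difference of that size, is argued against by 11 S phase genes, whose median was 0.27 (SD 0.64). Of these 6 were higher in EC and 2 lower, Ccne2 (-1.15) and Pcna (-1.06), both well short of the histone median. A smaller difference in cycling is not excluded, as 8 genes of the cell-cycle list were higher and 11 lower in EC. A difference in RNA selection was not decided, since the median of -3.16 for small RNA genes restates the pattern. Rn45s, also without a poly(A) tail, went the other way (5.77% and 5.34% of EC counts, 0.118% to 0.200% of CM counts). Preparation and cell type cannot be told apart here, and both stay open.

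Endothelial transcripts in CM libraries could come from endothelial cells collected with cardiomyocytes. A shared source would put every marker at about the same share, and the quartiles of the CM to EC levels lay 2.001-fold apart (bootstrap over 24 genes, 95% interval 1.46 to 3.36). This ratio just passed the bound of 2 set for it, and the interval, added after the ratio was seen, spans that bound, so the test decided neither way. The CM to EC levels within the list ran from 5.58% for Eng to 55.6% for Cldn5, with a median of 16.8%. For the 20 endocardial genes, for which no bound was set, the quartiles lay 2.91-fold apart. Their levels ran from 1.76% for Hapln1 to 217% for Cytl1, with a median of 14.8%. A source in endothelial cells of another composition than the sorted EC stays open.

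Het-selective ATAC regions outnumbered ko-selective ones 1.78-fold. With lists of equal length the ratio was 1.03, as was predicted if peak yield made the excess. Equal lists would also hide a loss of open regions that lowered the ko peak number. The ratio thus cannot tell a technical difference in yield from an effect of genotype. Loss of GATA4 at its binding sites was predicted to give an occupancy odds ratio above every other split. This was not met: 1.24 lay inside the range of the other 9 splits (1.12 to 1.89, each taken above 1), and 5 of the 10 splits were as large. That decides neither way, since the other splits mix unlike list lengths, were turned above 1 and are too few. GATA4 lay at 192 of 3905 het-selective regions (4.92%), a share of 9.30% with stricter q and 0.538% without Tie2-Cre GATA4 replicate 3. The odds ratio was 1.35 (Fisher's exact p = 0.0162) with equal ATAC lists and full GATA4 lists, a setting chosen after seeing the data. That p takes regions as units and does not measure the spread between libraries, so it is no evidence for an effect of genotype. An effect at bound regions was not decided.

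The total of 6105 het-selective and ko-selective regions was reached by 7 of the 10 splits, with 10390 as the highest other, and the 10 splits are too few for a share under 0.05. For GATA4, the total of 15181 was reached by 1 of 10 splits, the real one. The highest other, 13101, exchanged the libraries numbered 2, which had the fewest peaks; there too the splits are too few.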
